A study of Mus musculus with 8 samples.

How the data were processed

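Total RNA from the cerebellum and the tibialis anterior (TA) muscle of SCA17 knock-in (KI) and wild-type (WT) mice aged 3 months was labelled with biotin and hybridised to Affymetrix Mouse Gene 1.0 ST arrays. The deposited values were log2 expression values, 1 per probe set and array, made by the authors with GCOS and RMA per the submitters' processing notes. RMA corrects the background, normalises arrays to a common distribution of intensities and summarises the probes of a set by median polish; the versions, the filters, the genome build and which arrays were normalised together are not given in the sources used here. The table held 35556 probe sets on 8 arrays. The study text names 3 mice of each genotype, and 2 arrays per genotype and tissue were analysed here.

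Gene symbols were taken from the annotation of the array platform, which listed 23410 of the 35556 probe sets. Of these, 21789 carried 1 gene symbol and 1621 carried several, and 12146 probe sets of the table carried none. The 21789 probe sets named 19938 genes. Where a gene had several probe sets, the one with the highest mean over the 8 arrays was used. Chromosome names were taken from a RefSeq gene table (assembly GRCm38.p6); no coordinates are given, since the deposited table names no genome build. A gene was tested in a tissue when at least 2 of its 4 arrays were at or above the 40th percentile of all probe sets on the same array, which kept 13933 genes in muscle and 13641 in the cerebellum. The comparison between tissues and the test of the difference between tissues used the 14708 genes kept in either.

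One linear model with a mean for each of the 4 groups (KI cerebellum, WT cerebellum, KI muscle, WT muscle) was fitted per gene with limma 3.58.1 in R 4.3.3. The variances were moderated by eBayes, with 4 residual and 5.30 prior degrees of freedom. Genotype was compared within each tissue as KI minus WT, the difference between tissues as the muscle effect minus the cerebellum effect, and tissue as the mean of the muscle groups minus the mean of the cerebellum groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and for tissue also at a change of at least 2-fold. All adjusted p values for genes come from this limma fit. Errors given with a log2 difference are standard errors from the fit, and errors given with a group level are SD over 2 arrays. Numbers in the sample titles recur between the tissues, but no source says that they are animals, so arrays were not paired.

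Lists of genes for muscle fibre types, contraction, energy metabolism, stress responses, signalling pathways and the cell types of both tissues were written, with the tests above, before the data were examined. They were tested with limma's camera, which compares the members of a list with all other tested genes, at its preset correlation of 0.01 between members; 39 lists with at least 5 tested members were tested per tissue and adjusted together. Camera with a correlation estimated from the arrays, and fry, which asks whether the genes of a list move in one direction, were run as alternatives. The version with an estimated correlation was fitted again to the log2 values, so it differs from the main one in more than the correlation. For excitation-contraction coupling in muscle the estimated correlation was -0.0187, below the preset one. Its unadjusted camera p still rose from 0.000105 to 0.0137. A pass lost in that version therefore cannot be laid to correlation alone. List counts are also given adjusted over the list alone. The named genes followed a rule fixed at the same time. It takes Tbp, Manf and Myod1 first. It adds up to 12 genes with the largest rise and 12 with the largest fall among those called, at least 1.5-fold changed and with no overlap between the arrays of the genotypes. For each list described it takes up to 4 members with the smallest unadjusted p, for the difference between tissues the 5 largest changes each way, and for tissue the 5 largest each way. Genes named outside the rule are marked as chosen after their values were seen.

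The procedure was tested on simulated data in which 200 of 14708 genes were changed in each of 10 draws. The spread of each gene was drawn from the distribution of variances that eBayes fitted to these arrays, and was not the gene's own. In the muscle comparison it recovered 34.0% of genes changed 1.5-fold, 87.6% of those changed 2-fold and 95.6% of those changed 3-fold. In the cerebellum comparison it recovered 29.7%, 86.7% and 97.0% at the same folds. In the test of the difference between tissues it recovered 2.84%, 47.5% and 93.8%. In the tissue comparison it recovered 99.3% of 3-fold and 99.6% of 4-fold changes. False calls made up 5.55% of the calls in muscle, 4.76% in the cerebellum and 4.97% for the difference. In draws with no changed gene, a call was made in 0 of 10 draws for muscle, 1 for the cerebellum and 3 for the difference. Lists shifted by 1.25-fold were recovered in 9 of 9 draws in each tissue over the 14708 genes of the fit. The noise was normal with the same spread in all groups, as the fit assumes, and was drawn independently for each gene. The shares of false calls therefore show how the procedure behaves where its model holds, and not whether these arrays meet that model. Nor do the draws show how the list tests behave when the members of a list are correlated, as estimated from the arrays.

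The alternatives tried were no filter and a filter at the 60th percentile, eBayes with a trend and robust variances, array quality weights, quantile normalisation again within each tissue, subtraction of array medians, the mean of a gene's probe sets, all probe sets of the table, and each array left out in turn. Others were the number in the title as a replicate block, the 4 arrays of a tissue alone, other thresholds, and for lists the other tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probe sets with no symbol or with several were left out of the gene comparisons, since they name no single gene.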

Results

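Gene expression was measured on 8 arrays from SCA17 KI and WT mice aged 3 months. SCA17 is a dominant ataxia caused by an expanded polyglutamine tract in TBP, the TATA-box-binding protein used by all nuclear RNA polymerases. The arrays formed 4 groups of 2: KI cerebellum (replicates 94 and 97), WT cerebellum (95 and 96), KI muscle (94 and 97) and WT muscle (95 and 96). Array medians lay between 5.40 and 5.51 on the log2 scale, and the arrays of a group correlated over probe sets with r from 0.977 to 0.989, where probe sets are not independent replicates. The highest r of each array with an array of the other genotype in the same tissue was from 0.973 to 0.989. The median SD over genes was 0.0989 in KI cerebellum, 0.0819 in WT cerebellum, 0.0916 in KI muscle and 0.101 in WT muscle (n = 2 each). The p values rest on the spread within the 4 groups of 2 arrays, pooled in 1 fit, and the number of arrays limits the precision. Xist, the RNA that silences an X chromosome, was between 9.34 and 10.44 on all 8 arrays, while the Y-linked genes Kdm5d, Uty and Eif2s3y reached at most 3.90.

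The first comparison asked which genes differ between the muscle of KI and WT mice. Gdpd3, a phosphodiesterase of lysophospholipids (probe set 10557470), rose 7.84-fold in KI muscle, from a log2 level of 4.86 ± 0.17 in WT, below the 40th percentile of the arrays, to 7.83 ± 0.20 (SD, n = 2; adjusted p = 0.000861). Serpinb1a, an inhibitor of neutrophil proteases, rose 6.45-fold from 5.09 ± 0.43 to 7.78 ± 0.07 (SD, n = 2; adjusted p = 0.0012). Mss51, a mitochondrial protein of skeletal muscle (probe set 10417887), was 5.74-fold lower, at 5.96 ± 0.07 in KI against 8.48 ± 0.78 in WT (SD, n = 2; adjusted p = 0.00369). Myl3, the slow and ventricular essential myosin light chain, was 5.11-fold lower (log2 difference -2.35 ± 0.30, SE; adjusted p = 0.00638). Of 13933 genes tested, 495 passed an adjusted p of 0.05 in limma, 371 of them higher and 124 lower in KI muscle, and 353 of the 495 were changed at least 1.5-fold. At an unadjusted p under 0.05 there were 2822 genes.

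Other genes with large rises included H2-Ea, a class II histocompatibility gene on chromosome 17 like Tbp (4.57-fold), and Ampd3, an AMP deaminase (3.73-fold). Musk, the kinase that organises the neuromuscular junction, rose 3.41-fold, and Casq2, the calcium-storing calsequestrin of slow and cardiac muscle, rose 3.25-fold. Ttc9 (3.52-fold), Lix1 (3.04-fold), Tecrl (3.14-fold), the cone opsin Opn1mw (2.98-fold), the GTPase Rhou (2.98-fold) and the interferon-induced Ifit1 (2.95-fold) completed the 12 largest rises. The strain background of the animals is not given in the sources used here. The WT levels of Gdpd3, H2-Ea, Tecrl, Lix1 and Opn1mw were below the 40th percentile of their arrays, so the size of these folds depends on the background of the array. The precursor gene of the muscle microRNA miR-133a, Mir133a-1, was 3.52-fold lower, and Nmrk2, a nicotinamide riboside kinase, was 3.39-fold lower. Kcng4, a modifier subunit of potassium channels (2.86-fold), Dkk3 (2.73-fold), the myosin light chain kinase family member Mylk4 (2.71-fold), the methyltransferase Mettl21e (2.60-fold) and Smox, spermine oxidase (2.59-fold), fell as well. Tpbgl (2.57-fold), the actin-oxidising enzyme Mical2 (2.55-fold) and the LIM-domain protein Fhl3 (2.50-fold) completed the 12 largest falls. Adjusted p for these 24 genes ran from 0.000861 for Gdpd3 to 0.0284 for Mettl21e, and in each of them both KI arrays lay on the same side of both WT arrays.

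**Figure D1:**
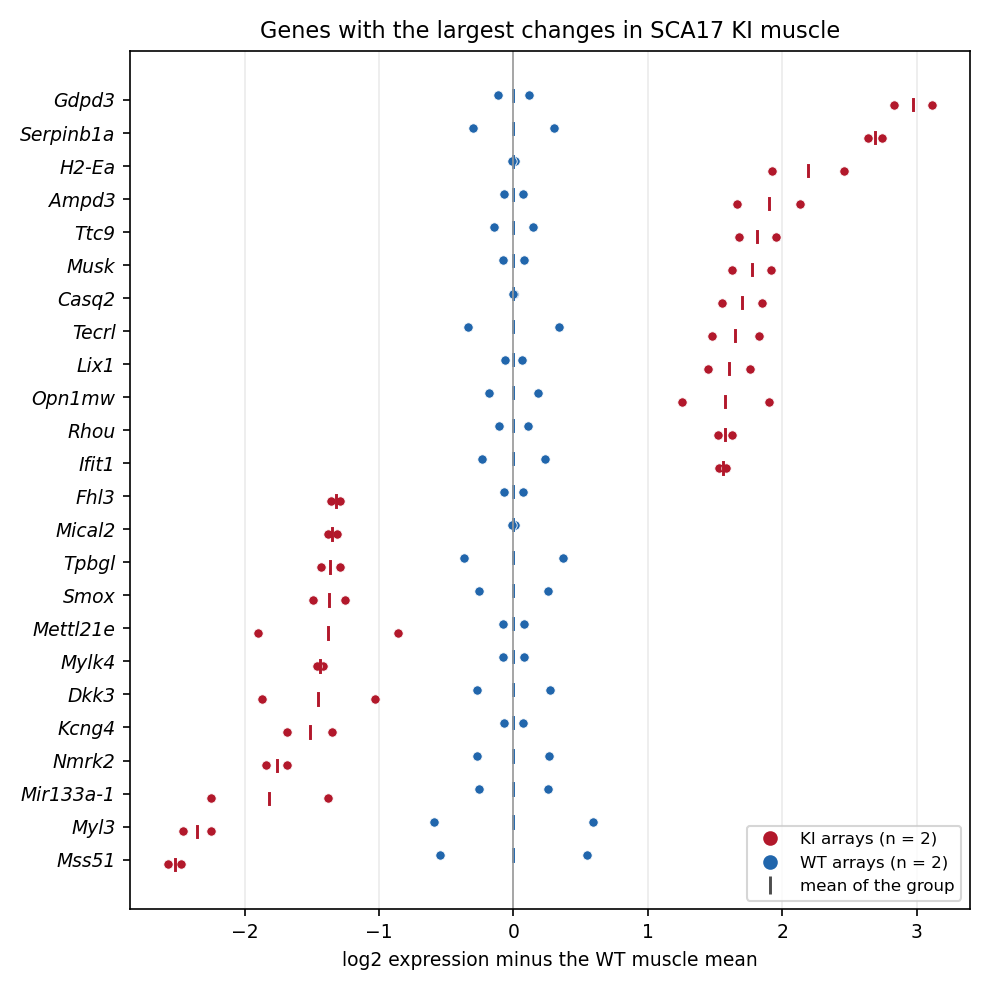
Log2 expression of the 24 genes with the largest called changes in KI muscle, as the difference of each array (points, 2 KI and 2 WT) from the WT muscle mean, with group means as vertical ticks. Gdpd3 lies 2.97 above the WT mean and Mss51 lies -2.52 from it.

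Tbp itself (probe set 10441973) was at 6.87 ± 0.10 in KI and 6.76 ± 0.08 in WT muscle (SD, n = 2; log2 difference 0.11 ± 0.12, SE; adjusted p = 0.634). The probe set measures Tbp RNA and does not tell the expanded from the normal allele. Myod1, the myogenic transcription factor, differed by 0.02 ± 0.13 (adjusted p = 0.962) and Manf, a neurotrophic factor of the endoplasmic reticulum, by -0.03 ± 0.16 (SE; adjusted p = 0.936). Over all tested genes, 50.2% had both KI muscle arrays above or both below the WT arrays, where chance gives 33.3%. All 495 called genes were without overlap. The count fell to 123 without KI muscle replicate 94, 114 without KI muscle replicate 97, 108 without WT muscle replicate 95 and 174 without WT muscle replicate 96, and to 264 without WT cerebellum replicate 95 or WT cerebellum replicate 96. It was 246 with no filter, 69 over all probe sets, 155 with the muscle arrays alone and 995 at an adjusted p of 0.1.

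Genes of fast-twitch contraction were lower in KI muscle. All 15 tested members had negative differences (median log2 -0.48), and 4 fell past the threshold, or 9 adjusted over the list alone: Casq1, the fast-muscle calsequestrin (-0.68 ± 0.12, adjusted p = 0.0199), Actn3, the fast-fibre actinin (-0.60 ± 0.13, 0.0372), Tnni2, fast troponin I (-0.55 ± 0.12, 0.0409), and Pvalb, the calcium buffer parvalbumin (-0.59 ± 0.13, 0.0439; log2 ± SE, n = 2 per group). Each of the 4 lost its call without any 1 of the muscle arrays (adjusted p from 0.0760 to 0.192) and with the muscle arrays alone (0.0501 to 0.109). The list passed camera in limma with adjusted p = 4.06e-08, but adjusted p = 0.268 with an estimated correlation, and fry gave 0.0218. The slow-twitch list did not pass (adjusted p = 0.933). Casq2 rose by 1.70 ± 0.16, Myl3 fell by 2.35 ± 0.30, and Myoz2 (0.70 ± 0.28, adjusted p = 0.198) and Ankrd2 (0.66 ± 0.26, 0.195) did not pass. Of the 12 members 1 was called higher and 1 lower, also adjusted over the list alone.

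Genes of excitation-contraction coupling and of glycolysis were lower too. In the coupling list 4 of 18 members fell, 4 also adjusted over the list alone: Casq1, the junctophilins Jph2 (-0.64 ± 0.11, adjusted p = 0.0202) and Jph1 (-0.50 ± 0.11, 0.0405), and Cacna1s, the voltage sensor of the fibre (-0.54 ± 0.11, 0.0328). These calls too were lost without any 1 muscle array (0.0570 to 0.172) and with the muscle arrays alone (0.0501 to 0.111). The list passed with adjusted p = 0.00103, but adjusted p = 0.268 with an estimated correlation, and fry gave 0.0218. It shares 2 tested genes, Atp2a1 and Casq1, with the fast-twitch list. In the glycolysis and creatine kinase list 4 of 18 members fell, 5 adjusted over the list alone, where 1 was higher. They were Ampd1, the muscle AMP deaminase (-1.01 ± 0.20, adjusted p = 0.032), Pgam2, the muscle phosphoglycerate mutase (-0.87 ± 0.14, 0.017), Gpd1, glycerol-3-phosphate dehydrogenase (-0.78 ± 0.11, 0.011), and Phka1, a phosphorylase kinase subunit (-0.75 ± 0.12, 0.0135). Ampd1 lost its call without any 1 muscle array (0.0770 to 0.161), and Pgam2 (all but KI replicate 97), Gpd1 and Phka1 (all but WT replicate 95) lost theirs without 3 of the 4 (0.0520 to 0.0865). That list passed with adjusted p = 3.00e-06, but adjusted p = 0.339 with an estimated correlation, and fry gave 0.0341.

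Oxidative phosphorylation genes were also lower as a list. None of 30 members passed in limma (0 also adjusted over the list alone; 4 had an unadjusted p under 0.05 and 25 had negative differences, median log2 -0.12). The members with the smallest p were Ndufs1 (-0.41 ± 0.13, adjusted p = 0.117), Uqcrc1 (-0.37 ± 0.11, 0.112), Ndufs3 (-0.37 ± 0.11, 0.102) and Uqcrfs1 (-0.35 ± 0.14, 0.192), all subunits of respiratory complexes. The list passed camera with adjusted p = 0.00139, but adjusted p = 0.616 with an estimated correlation. It did not pass with fry (0.351) or without KI muscle replicate 94 (0.269). Its mean was -0.237 in KI replicate 94 and -0.037 in KI replicate 97, against 0.016 and -0.016 in the WT arrays. Of 10 potassium and sodium channel genes, 2 fell, or 5 adjusted over the list alone: Kcnc1 (-0.80 ± 0.12, adjusted p = 0.0126) and Kcnd2 (-0.63 ± 0.14, 0.0401). Kcnc1 was not called without WT muscle replicate 95 (0.0787) or KI muscle replicate 97 (0.0732), nor Kcnd2 without KI muscle replicate 94 (0.137) or KI muscle replicate 97 (0.134). Kcnab1 (-0.47 ± 0.12, 0.072) and Kcnd3 (-0.41 ± 0.11, 0.0732) did not pass, and the KI levels of Kcnd2 were below the 40th percentile of their arrays. That list passed with adjusted p = 0.022, but adjusted p = 0.339 with an estimated correlation, and fry gave 0.0218. It did not pass after another quantile normalisation (0.0589), on ranks (0.138), or without WT muscle replicate 95 (0.0863), WT muscle replicate 96 (0.0862) or KI muscle replicate 97 (0.0572).

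Several genes that respond to denervation were higher. Of 13 tested members 5 rose, or 7 with 1 lower adjusted over the list alone: Musk (1.77 ± 0.14), the acetylcholine receptor subunits Chrna1 (1.31 ± 0.23, adjusted p = 0.0202) and Chrnb1 (0.84 ± 0.16, 0.0258), and the transcription factor Runx1 (0.95 ± 0.12, 0.00576) among them. The list did not move in 1 direction: 7 members had positive and 6 had negative differences, Myog among the negative. Both KI arrays lay above both WT arrays in 7 members and below them in 5. Chrna1 and Chrnb1 lost their calls without any 1 muscle array (0.0507 to 0.124), while Musk and Runx1 were called in all 18 alternatives. The list did not pass camera (adjusted p = 0.0895; 0.553 with an estimated correlation), while fry gave 0.00698. Of 12 neuromuscular junction genes, 2 rose, Musk and Lrp4, the receptor of agrin (0.75 ± 0.11, adjusted p = 0.00942). Adjusted over the list alone it was 2 higher and 1 lower. Lrp4 was not called without WT muscle replicate 96 (0.0501) or KI muscle replicate 97 (0.0584). Chrne, the adult receptor subunit (-0.46 ± 0.11, 0.0598), and Ufsp1 (-0.30 ± 0.13, 0.241) did not pass. The list did not pass camera (adjusted p = 0.813) but passed fry (0.044). Among 13 myogenic regulators only Tead4 passed (0.52 ± 0.11, adjusted p = 0.040; 1 adjusted over the list alone), and not without any 1 muscle array (0.0948 to 0.182). Myog (-0.47 ± 0.17, 0.159), Mymk (0.37 ± 0.14, 0.178) and Myf6 (0.30 ± 0.11, 0.179) did not pass, and the list gave adjusted p = 0.861. None of 20 atrophy and autophagy genes passed (0 adjusted over the list alone, 6 at an unadjusted p under 0.05; limma, list adjusted p = 0.919). Fbxo32, the ubiquitin ligase atrogin-1, was at -0.43 ± 0.12 (0.0897), Foxo1 at -0.59 ± 0.21 (0.154), Zfand5 at -0.36 ± 0.13 (0.164) and the autophagy receptor Sqstm1 at 0.38 ± 0.13 (0.143).

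Interferon response genes were higher in KI muscle. Of 12 tested members 8 rose, and 8 adjusted over the list alone (median log2 1.02): the transcription factor Irf7 (1.27 ± 0.20, adjusted p = 0.0137), Oasl2 (1.25 ± 0.19, 0.0126), the ISG15 protease Usp18 (1.11 ± 0.14, 0.00628) and the RNA sensor Ddx58 (0.92 ± 0.14, 0.0126) had the smallest p. Irf7 lost its call without any 1 muscle array (0.0590 to 0.0692), and Oasl2 (all but WT replicate 95) and Ddx58 (all but WT replicate 96) without 3 of the 4 (0.0529 to 0.0738). The list passed with adjusted p = 9.87e-08, but adjusted p = 0.317 with an estimated correlation, and fry gave 0.0218. Markers of macrophages were also above WT in 12 of 14 genes (median log2 0.27), with none passing in limma, 0 adjusted over the list alone, 5 at an unadjusted p under 0.05 and a list adjusted p of 0.0685. The list passed without WT muscle replicate 95 (0.0329), without KI muscle replicate 97 (0.0157), on ranks (0.0468) and after another quantile normalisation (0.0336). C1qb was at 0.57 ± 0.22 (0.194), Lyz2 at 0.31 ± 0.13 (0.221), Itgam at 0.26 ± 0.11 (0.211) and Trem2 at -0.33 ± 0.12 (0.185).

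Polr2a, the largest subunit of RNA polymerase II, rose 2.34-fold in KI muscle (1.23 ± 0.12, adjusted p = 0.00158). With Taf2 (0.55 ± 0.12, 0.0378) and Taf1 (0.51 ± 0.11, 0.0387), subunits of the TBP-containing complex TFIID, it made 3 of 24 TBP complex and core transcription genes that rose, or 4 adjusted over the list alone. Polr2a was called in all 18 alternatives, while Taf1 and Taf2 lost their calls in 13 and 10 of 18, among them each muscle array left out (0.0871 to 0.184) and the muscle arrays alone (0.105 and 0.0865). Gtf2b was at 0.65 ± 0.17 (0.0716). The list did not pass (adjusted p = 0.124), except with no filter (0.0442). Of 18 heat shock chaperones 2 rose, or 4 adjusted over the list alone: Hsp90aa1 (0.61 ± 0.11, adjusted p = 0.0219) and the small heat shock protein Hspb1 (0.60 ± 0.12, 0.0328). Both lost their calls without any 1 muscle array (0.0811 to 0.126) and with the muscle arrays alone (0.0653 and 0.0660). Hspb7 (0.79 ± 0.19, 0.052) and Hspa1a (0.41 ± 0.12, 0.103) did not pass. Nor did the list (adjusted p = 0.0588), which passed without KI muscle replicate 94 (0.0342), with no filter (0.0122), with trended and robust variances (0.0426) and with the muscle arrays alone (0.0499). In all, 6 of the 39 lists passed camera in muscle, 1 higher and 5 lower, 0 with an estimated correlation, where 5 had an unadjusted p under 0.05. With fry 9 passed, 5 higher and 4 lower, and 5 of the 9 were among the 6.

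The second comparison asked the same in the cerebellum, the part of the brain affected in SCA17. Members of the interferon response list were among the genes that rose most: Ifit1 (probe set 10462623) rose 5.60-fold (log2 difference 2.49 ± 0.25, SE; adjusted p = 0.00728), and Oasl2 rose 4.88-fold from a log2 level of 5.28 ± 0.04 in WT to 7.57 ± 0.45 in KI (SD, n = 2; adjusted p = 0.00261). Lgals3bp, a secreted glycoprotein that binds galectin 3, rose 4.91-fold (2.29 ± 0.20, SE; adjusted p = 0.00262) and Usp18 rose 4.52-fold (2.18 ± 0.14; adjusted p = 0.000639). Il20rb, an interleukin receptor chain (probe set 10596041), was 2.22-fold lower, at 7.08 ± 0.11 in KI against 8.23 ± 0.15 in WT (SD, n = 2, adjusted p = 0.0159). The other probe sets of Il20rb had log2 differences of -1.19 (10596027) and -0.53 (10596034), so the size of the fall depends on the probe set. Oasl2 and Usp18 were called in all 18 alternatives, but Ifit1 not without WT cerebellum replicate 95 (0.0755) or 96 (0.0684), Lgals3bp not without KI cerebellum replicate 94 (0.0602) and Il20rb not without any 1 cerebellum array (0.0684 to 0.244). Of 13641 genes tested, 28 passed an adjusted p of 0.05 in limma, 20 higher and 8 lower in KI, all of them changed at least 1.5-fold. At an unadjusted p under 0.05 there were 727 genes, 5.33% of those tested, close to the share of 0.05 that chance alone gives.

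Further rises were seen in Ifit3 (3.82-fold), the antiviral membrane protein Ifitm3 (3.59-fold), Rtp4 (3.40-fold), Trim30a (2.94-fold), Ifi27 (2.60-fold), Gdpd3 (2.56-fold), Ddx58 (2.44-fold) and the GTPase Gbp3 (2.31-fold). The WT levels of Ifit1, Rtp4, Gdpd3 and Gbp3 were below the 40th percentile of their arrays, with the same limit on their folds. The adaptor Stap2 was 2.04-fold lower, Snrpe, a core protein of spliceosomal particles, 1.98-fold, the small nucleolar RNA Snord14e 1.95-fold and the kinase Sbk1 1.90-fold. The centriolar Cep76 (1.88-fold), Nab2, a corepressor of EGR factors (1.78-fold), and the lysosomal Creg1 (1.60-fold) completed the 8 genes that fell. Adjusted p for these 20 genes ran from 0.000639 for Usp18 and Ifitm3 to 0.0442 for Creg1. Tbp was at 7.60 ± 0.11 in KI and 7.78 ± 0.10 in WT cerebellum (SD, n = 2; -0.18 ± 0.12, SE; adjusted p = 0.998), Myod1 differed by 0.18 ± 0.13 (0.998) and Manf by -0.05 ± 0.16 (1.000). Over all tested genes 35.3% had no overlap between the genotypes, where chance gives 33.3%. The count fell to 3 without KI cerebellum replicate 94, 4 without WT cerebellum replicate 95, 5 without WT cerebellum replicate 96 and 6 without KI cerebellum replicate 97, to 18 with no filter and to 6 over all probe sets. At an unadjusted p under 0.01 and at least 1.5-fold it was 86, of which 39 were higher and 47 lower.

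The interferon response list was higher as a whole. Of 10 tested members 6 rose, or 7 adjusted over the list alone, and all 10 had positive differences (median log2 1.53), with Ifit1 (2.49 ± 0.25), Oasl2 (2.29 ± 0.19), Usp18 (2.18 ± 0.14) and Ddx58 (1.29 ± 0.14, adjusted p = 0.00924) having the smallest p. Ddx58 lost its call without any 1 cerebellum array (0.0591 to 0.191). It passed with adjusted p = 4.90e-25, but adjusted p = 0.115 with an estimated correlation, and fry gave 0.0209. All 12 tested markers of macrophages and microglia had positive differences as well (median log2 0.28), led by the protease Ctss (0.77 ± 0.17, adjusted p = 0.263), with Csf1r (0.36 ± 0.15, 0.901), Fcer1g (0.31 ± 0.13, 0.901) and C1qa (0.31 ± 0.14, 0.941). None passed in limma, where 3 had an unadjusted p under 0.05, and 1 did adjusted over the list alone. The list passed with adjusted p = 3.49e-06, but adjusted p = 0.298 with an estimated correlation and 0.249 with fry.

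Genes expressed by Purkinje cells, the output neurons of the cerebellar cortex, were lower in KI. All 21 tested members had negative differences (median log2 -0.50), and in 17 of them both KI arrays were below both WT arrays, where chance leaves 33.3% of genes without overlap in either direction. The members with the smallest p were Inpp5a, an inositol phosphatase (-0.70 ± 0.11, adjusted p = 0.0612), Pcp2 (-0.89 ± 0.17, 0.148), the G-protein regulator Rgs8 (-0.73 ± 0.14, 0.153) and Pvalb (-0.57 ± 0.13, 0.310). None passed in limma over all genes, 12 were lower adjusted over the list alone, and 13 had an unadjusted p under 0.05. The list passed with adjusted p = 9.55e-20, but adjusted p = 0.372 with an estimated correlation and 0.249 with fry. Its mean was -0.63 in KI cerebellum replicate 94 and -0.34 in replicate 97, relative to the WT mean.

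Genes of granule cells, the most numerous neurons of the cerebellum, were also lower as a list. All 16 members had negative differences (median log2 -0.20), of which 2 had an unadjusted p under 0.05, with Cbln3 at -0.45 ± 0.13 (adjusted p = 0.551), Neurod1 at -0.37 ± 0.17 (0.934), Kcnd2 at -0.36 ± 0.14 (0.824) and Gabrd at -0.26 ± 0.13 (0.990). None passed in limma or adjusted over the list alone (0 genes). The list passed with adjusted p = 0.000204, but adjusted p = 0.682 with an estimated correlation, 0.705 with fry and 0.563 without KI cerebellum replicate 94. Its mean was -0.352 in that array and -0.060 in KI replicate 97, against 0.029 and -0.029 in the WT arrays, and replicate 94 also had the highest means of choroid plexus (0.45) and hindbrain markers (0.48). Calcium channel and signalling genes, 2 of whose 15 tested members are also in the Purkinje list, passed as lower with adjusted p = 0.00403, but adjusted p = 0.782 with an estimated correlation, 0.765 with fry, 0.765 without KI cerebellum replicate 94 and 0.0867 without WT cerebellum replicate 96. Their mean was -0.309 in KI replicate 94 and -0.051 in KI replicate 97, against -0.048 and 0.048 in the WT arrays. None of them was called in limma, 2 had an unadjusted p under 0.05 and 1 was lower adjusted over the list alone: Plcb3 was at -0.67 ± 0.14 (0.224), Camk4 at -0.43 ± 0.18 (0.889), Camk2b at -0.22 ± 0.12 (0.998) and Plcb4 at -0.22 ± 0.12 (0.998).

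Choroid plexus markers, which report on tissue lining the ventricle beside the cerebellum, had positive differences in all 10 genes (median log2 0.24), 1 at an unadjusted p under 0.05, with Kl at 0.46 ± 0.26 (adjusted p = 0.998), Kcnj13 at 0.31 ± 0.23 (0.998), Calml4 at 0.28 ± 0.12 (0.918) and Aqp1 at 0.23 ± 0.14 (0.998). None passed in limma or adjusted over the list alone (0 genes). The mean of the list was 0.45 in KI replicate 94 but 0.03 in KI replicate 97, between the WT arrays (-0.16 and 0.16), and in 2 of the 10 genes both KI arrays were above both WT arrays. The list passed with adjusted p = 0.00533, but adjusted p = 0.782 with an estimated correlation, 0.884 with fry, 0.654 without KI cerebellum replicate 94 and 0.482 without WT cerebellum replicate 95. Heat shock chaperones were lower, with 14 of 17 negative and none called in limma (1 lower adjusted over the list alone, 3 at an unadjusted p under 0.05): the small heat shock protein Cryab was at -0.46 ± 0.10 (0.310), Bag3 at -0.34 ± 0.13 (0.857), Dnajb1 at -0.32 ± 0.13 (0.889) and Hspb6 at 0.21 ± 0.11 (0.998). That list passed with adjusted p = 0.0113, but adjusted p = 0.774 with an estimated correlation, 0.415 with fry, 0.482 without WT cerebellum replicate 95 and 0.221 without KI cerebellum replicate 97. Of 24 TBP complex and core transcription genes, Polr2a rose (0.82 ± 0.12, adjusted p = 0.0282; 1 adjusted over the list alone), though it was not called without any 1 cerebellum array (adjusted p up to 0.350). Gtf2a2 was at -0.25 ± 0.13 (0.994) and Taf5 at -0.21 ± 0.14 (0.998). The list gave adjusted p = 0.819. In all, 7 of the 39 lists passed camera in the cerebellum, 3 higher and 4 lower, 0 with an estimated correlation, where 3 had an unadjusted p under 0.05, and 1 with fry.

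**Figure D2:**
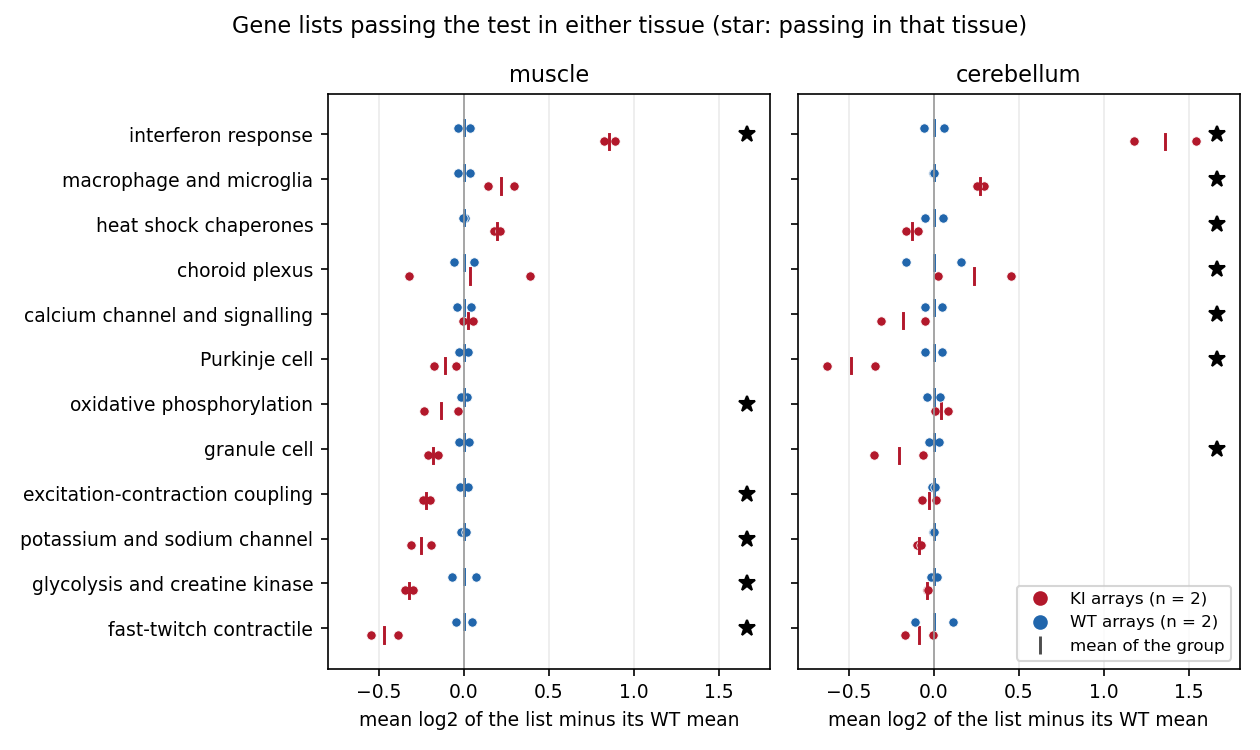
Mean log2 expression of the tested members of 12 lists as the difference of each array (points, 2 KI and 2 WT per tissue) from the WT mean of that tissue, with group means as vertical ticks and a star where the list passed camera in that tissue. The interferon response list lies between 1.18 and 1.54 in the KI cerebellum arrays and the Purkinje list between -0.63 and -0.34.

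Genes called in both tissues were counted to ask whether the genotype had a common effect. Of 12866 genes tested in both, 16 were higher in both, where 0.502 would be shared if the calls were independent, 2 were lower in both, where 0.0659 would be shared, and 0 were called in opposite directions in limma. The fit gave a gene the same standard error in both tissues, so its calls were not independent. The expected numbers therefore do not give what chance would share. At an unadjusted p under 0.05 in both tissues, 137 genes had the same direction and 70 had opposite ones. Ifit1, Ifit3, Oasl2, Usp18, Rtp4, Ddx58, Ifitm3, Trim30a, Gbp3, Irgm1, Eif2ak2, Rnf213, Lgals9, B2m, Gdpd3 and Polr2a were higher, and Snrpe and Snord14e were lower. Those of them outside the rule were chosen after their values were seen. Usp18 rose 2.16-fold in muscle against 4.52-fold in the cerebellum, and the difference between tissues did not pass (adjusted p = 0.0915). The 16 genes became 11 with no filter, 2 over all probe sets and 9 with each tissue fitted alone. They became 2 without WT muscle replicate 95, 3 without KI muscle replicate 97 or without any of KI cerebellum replicate 94, WT cerebellum replicate 95 and WT cerebellum replicate 96, 4 without KI cerebellum replicate 97, and 5 without KI muscle replicate 94 or WT muscle replicate 96. The 2 lower genes became 0 with no filter, over all probe sets, and without any 1 of the 4 cerebellum arrays, WT muscle replicate 95 or WT muscle replicate 96. They became 1 without KI muscle replicate 94 or KI muscle replicate 97 and with each tissue fitted alone.

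**Figure D3:**
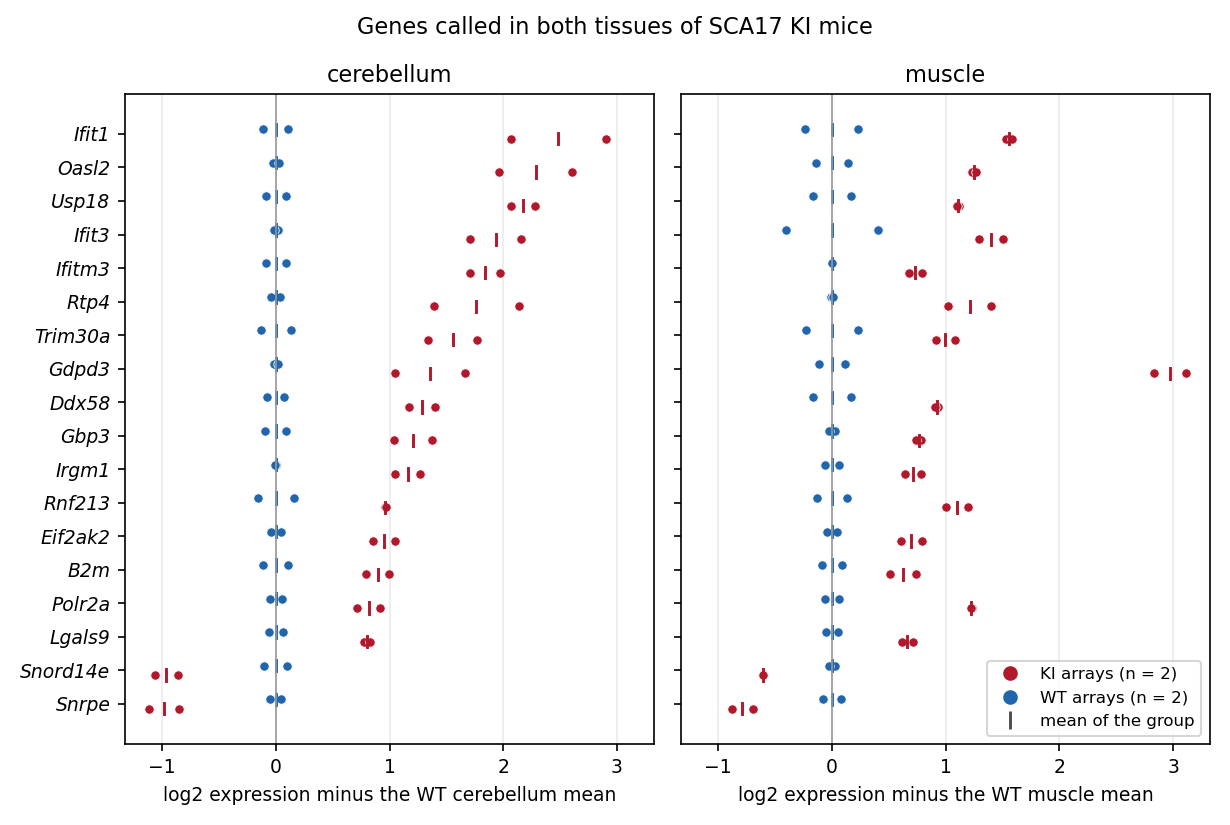
Log2 expression of the 18 genes called in both tissues, as the difference of each array (points, 2 KI and 2 WT per tissue) from the WT mean of the tissue, with group means as vertical ticks. Ifit1 lies 2.49 above the WT mean in the cerebellum and 1.56 above it in muscle, and Snrpe lies -0.98 and -0.79 from it.

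The third comparison asked which genotype effects differ between the tissues. Serpinb1a rose in muscle (2.69) and was at -0.22 in the cerebellum, a difference of 2.91 ± 0.29 (log2 ± SE; adjusted p = 0.0342), and Casq2 differed by 2.12 ± 0.23 (adjusted p = 0.0342). Ampd3 (1.82 ± 0.23), Lix1 (1.72 ± 0.25) and Ttc9 (1.72 ± 0.23) also had the higher effect in muscle. Nmrk2 (-1.96 ± 0.25), Mylk4 (-1.58 ± 0.23), Agbl1 (-1.39 ± 0.18), Fhl3 (-1.29 ± 0.17) and Mical2 (-1.17 ± 0.15) had the lower effect in muscle, and Nmrk2, Mylk4, Agbl1 and Fhl3 did not pass the filter in the cerebellum. In all, 21 of 14708 genes passed in limma, 15 with the higher effect in muscle and 6 with the lower, against 2033 at an unadjusted p under 0.05. None of the 21 was left over all probe sets (0 in limma, 2459 at an unadjusted p under 0.05), and 3 genes passed with no filter, 38 with the 60th percentile and 63 with robust and trended variances. The count was 0 without KI cerebellum replicate 94, WT cerebellum replicate 95, WT cerebellum replicate 96 or KI muscle replicate 97, with 2114, 1220, 1688 and 1701 genes at an unadjusted p under 0.05, was 1 without KI cerebellum replicate 97, and was 3 without WT muscle replicate 95 or WT muscle replicate 96. With the number in the title as a replicate block it was 14, of which 8 were among the 21. Lix1, Mical2, Fhl3 and Agbl1 were not called in that fit, in which each number recurs with 1 genotype in both tissues.

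The tissues themselves differed in 3823 of 14708 genes at 2-fold or more, 1615 higher in muscle and 2208 higher in the cerebellum (n = 4 per tissue). The largest differences were the muscle genes Myh1 (7.63 ± 0.13), Myl1 (7.45 ± 0.12), Xirp2 (7.39 ± 0.14), Myot (7.21 ± 0.10) and Car3 (7.14 ± 0.12; log2 ± SE). The neuronal genes Gabra6 (-7.11 ± 0.10), Neurod1 (-6.72 ± 0.12), Calb1 (-6.47 ± 0.09), Vsnl1 (-6.14 ± 0.19) and Calb2 (-6.09 ± 0.12) were largest the other way, and adjusted p for the 10 genes was at most 2.58e-09. Myh1, a fast myosin heavy chain, was at 11.37 ± 0.32 in KI and 11.92 ± 0.13 in WT muscle (SD, n = 2) and at 4.12 and 3.90 in the cerebellum of KI and WT.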

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

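The tests in this part were chosen after the results were seen, except the count of splits of the 8 arrays for the comparison of tissues, the test of the difference between tissues for genes and the tests of lists within a tissue, which were set before. Permutations, bootstrap intervals, Fisher's exact tests and matched random sets over genes treat genes as independent, which they are not. They measure the spread over genes and not the spread between animals or arrays.

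The genotype effect differed between muscle and cerebellum for 21 genes, of which the rule named 10. With the number in the title as a replicate block 8 of the 21 were called, and without KI cerebellum replicate 94, WT cerebellum replicate 95, WT cerebellum replicate 96 or KI muscle replicate 97 the count was 0 (limma; 2114, 1220, 1688 and 1701 genes at an unadjusted p under 0.05). Serpinb1a (2.91), Casq2 (2.12), Ampd3 (1.82), Lix1 (1.72) and Ttc9 (1.72) had the higher log2 effect in muscle, and Mical2 (-1.17), Fhl3 (-1.29), Agbl1 (-1.39), Mylk4 (-1.58) and Nmrk2 (-1.96) the lower one. By camera, 8 of 39 lists differed between the tissues, 0 with an estimated correlation (lowest adjusted p = 0.526; limma; 2 at an unadjusted p under 0.05). The muscle effect was below the cerebellum effect for the fast-twitch, glycolysis, oxidative phosphorylation, excitation-contraction coupling, embryonic and neonatal contractile, and interferon response lists, and above it for the heat shock and Purkinje lists. The medians of the interferon list were 1.02 over 12 genes in muscle and 1.53 over 10 genes in the cerebellum. Those of the Purkinje list were -0.12 over 16 genes and -0.50 over 21. The median of the difference itself was -0.316 for the 12 interferon genes and 0.286 for the 21 Purkinje genes.

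Among probe sets that name no single gene, which entered the report only in its counts over all probe sets, 8 of 6609 passed the threshold in muscle and 1 of 6764 passed it in the cerebellum when fitted with all other probe sets. Adjusted over these probe sets alone, 3 passed in muscle, all higher in KI, and 0 in the cerebellum (limma), where 302 had an unadjusted p under 0.05.

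Other splits of the arrays were counted for each comparison of groups. Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one by tissue, gave as many genes (3822 in a fit with 2 groups, against 0 in the highest other split in limma, where 837 genes at most had an unadjusted p under 0.05). Every other split mixed the tissues within its groups, which by itself lowers the count, so the splits cannot exclude chance. The 4 arrays of a tissue allow 3 splits, too few for a share under 0.05: only 1 gave as many genes as the real one in muscle (495, highest other 0) and only 1 in the cerebellum (28, highest other 0). The splits that mixed genotypes had 490 and 503 genes at an unadjusted p under 0.05 in muscle, against 2822 for the real one. In the cerebellum the split that put KI replicate 94 with WT replicate 95 had 961, more than the 727 of the real split, and the remaining split had 216.

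Interferon response genes were higher in KI in both tissues, with a median log2 change of 1.53 in the cerebellum, but with an estimated correlation the list did not pass there (adjusted p = 0.115) or in muscle (0.317). More macrophages or microglia would raise their markers too. These had a median of 0.276 in the cerebellum (permutation p = 0.0019, two-sided, with 0 genes in both lists). In muscle their median was 0.272, against 1.02 for the interferon genes (permutation p = 0.0008). This argues against more cells of unchanged expression as the whole cause. It cannot exclude added cells that are themselves richer in interferon genes. The markers were higher in 12 of 12 genes in the cerebellum and 12 of 14 in muscle. DNA carried along with the edited Tbp allele that changed only its own genes would place the rises on chromosome 17. Of the 16 genes higher in both tissues, 1 lies there. An effect of such DNA on genes of other chromosomes was not tested, so it stays open as a cause. H2-Ea, called in muscle and not tested in the cerebellum, lies on chromosome 17 too but is not among the 16. As the strain background is not given, carried-along DNA stays open for its rise. An infection or another exposure shared by the KI animals cannot be told apart from the genotype: the lower KI cerebellum array exceeded the higher WT array by 1.12 in the mean of the list, and housing is not given in the sources used here. A response of these genes to the mutation remains a hypothesis that may account for them. It was not separated from exposure, from carried-along DNA or from added cells richer in interferon genes.

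Purkinje cell genes were lower in KI cerebellum as a list (adjusted p = 9.55e-20 with camera; adjusted p = 0.372 with an estimated correlation). A lower share of all neurons would lower granule cell genes alike, but the Purkinje median lay -0.304 from the granule median (permutation p = 0.00118, two-sided), by -0.277 in KI replicate 94 and -0.284 in KI replicate 97. The brightness of the genes does not account for it, since 0% of 10000 random lists matched on mean expression had a median as low (lowest -0.15). Nor does a single array: the higher KI array lay 0.295 below the lower WT array in the mean of the list, while the WT arrays differed by 0.0965. Hindbrain tissue taken along with the cerebellum stays open: the list of vermis and hindbrain dissection markers did not pass (adjusted p = 0.188; 0.837 with an estimated correlation), but its mean was 0.483 in KI replicate 94, which had the lower Purkinje mean, against -0.080 in KI replicate 97 and -0.069 and 0.069 in the WT arrays. A lower expression or number of Purkinje cells in KI mice may account for the fall and was not separated from the dissection of the tissue.

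X-linked genes were more frequent among the genes called in KI muscle than among all genes: 31 of 387 were called, 30 of them higher, where 13.7 would be by chance (Fisher's exact p = 3.19e-05, two-sided; 0.000639 adjusted over 20 chromosomes). Without 1 array the X-linked calls were 8 without KI muscle replicate 94, 8 without WT muscle replicate 95, 13 without WT muscle replicate 96 and 7 without KI muscle replicate 97. In the cerebellum 0 of 415 were called in limma, where 0.852 would be by chance, and 22 (5.30%) had an unadjusted p under 0.05, against 5.33% of all genes. Brightness does not account for the excess in muscle, since 0.01% of 10000 gene sets matched on mean expression had as many calls, and without each muscle array in turn the highest Fisher's exact p was 0.0383. The median of all tested X-linked genes in muscle was 0.119, the highest of the 20 chromosomes, against 0.0240 for autosomal genes, an excess of 0.0946 (95% bootstrap interval over genes 0.0629 to 0.136). A gain in the dose of the whole chromosome in the KI animals would raise it in both tissues, but the excess in the cerebellum was 0.00782 (-0.00703 to 0.0260). The 30 genes higher in muscle had a median of 0.799 there, and the 23 of them tested in the cerebellum had one of 0.0386 (SD over genes 0.133). An equal shift of all X-linked genes in muscle is not the whole cause: with the excess taken from each of them, 27 were called where 13.6 would be by chance (Fisher's exact p = 0.000666), and 26 with its upper bound taken (p = 0.00171). With 1 muscle array left out as well, fewer genes were called and p was 0.0525 to 0.134, while the calls were 1.93 to 2.07 times those by chance, against 1.98 times with all arrays. A selective rise of some X-linked genes in KI muscle, of which the rule named Eda2r, Opn1mw and Taf1, may be followed up as a hypothesis, beside the smaller shift of the chromosome.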

How the results depend on the processing

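All alternatives were planned, and none was added. Of the called genes named, 57 in muscle, 21 in the cerebellum, 10 for the difference and 10 for tissue, none reversed, and 20, 3, 0 and 10 kept their call in every alternative that tested them. Of the 20 in muscle, 17 were tested in all 18; Gdpd3, H2-Ea and Lix1 did not pass the filter without either KI muscle array, nor Lix1 at the 60th percentile. The tissue count stayed between 3619 and 5338. In muscle (495) the count was 246 with no filter, 69 over all probe sets, 155 with the muscle arrays alone, 995 at an adjusted p under 0.1, and 108 to 393 without each array. In the cerebellum (28) it was 18 with no filter, 6 over all probe sets, 86 at an unadjusted p under 0.01 and 1.5-fold (39 higher, 47 lower), and 3 to 29 without each array. For the difference between tissues (21) it was 3 with no filter, 38 at the 60th percentile, 63 with trend and robust variances, 0 over all probe sets (limma; 2459 at an unadjusted p under 0.05), and 0 to 16 without each array. Over all probe sets and with no filter more tests were adjusted for, and leaving out an array leaves 1 array in a group, assumed to vary like the others. Whether these account for the changed counts was not tested, and other causes were not tested. After another quantile normalisation the muscle count was 396, 65.7% of them higher against 74.9%, and the difference count 25, 15 and 10 each way.

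Of the lists, 6 passed in muscle, 0 with an estimated correlation (5 at an unadjusted p under 0.05) and 6 to 14 without each array; 7 passed in the cerebellum, 0 with an estimated correlation (3 at an unadjusted p under 0.05), 1 with fry and 6 to 11 without each array (lists passing limma's tests). The cause was not tested. With the number in the title as a replicate block the counts were 494 in muscle, 27 in the cerebellum, 14 for the difference (8 of them among the 21) and 3823 for tissue, and 6 and 7 lists. Residuals of arrays with the same number correlated by 0.0566 in KI and -0.0965 in WT, and the consensus correlation was -0.0733, so the values gave no sign of a pairing. The signal over background limits genes near the floor of the array.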

Other observations

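The tests in this part were planned, and which lists to describe was chosen after the results were seen.

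Eda2r, a receptor of the tumour necrosis factor family induced by p53, rose 2.66-fold in KI muscle (log2 1.41 ± 0.16, SE; adjusted p = 0.00414), from 5.67 ± 0.29 in WT to 7.08 ± 0.17 (SD, n = 2). Zmat3, another p53 target, was higher by 0.52 ± 0.11 (adjusted p = 0.0337), but was not called without any 1 muscle array (0.0985 to 0.135). Trp53inp1 (0.68 ± 0.17, 0.0679) and Gadd45a (0.43 ± 0.17, 0.195) did not pass. Of the 13 tested p53 targets 2 rose, or 3 adjusted over the list alone, and the list did not pass camera in limma (adjusted p = 0.329; 0.0439 with fry). Its median was -0.03, while its mean was 0.21.

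Insig1, the sterol-regulated anchor of SREBP in the endoplasmic reticulum, rose 1.66-fold in KI muscle (0.73 ± 0.13, adjusted p = 0.0199), but was not called without any 1 muscle array (0.0539 to 0.117). Of 15 cholesterol synthesis genes, 14 had positive differences and 1 was called, or 3 adjusted over the list alone, with Nsdhl at 0.47 ± 0.14 (0.0986), Srebf2 at 0.41 ± 0.11 (0.0756) and Msmo1 at 0.35 ± 0.18 (0.305); the list did not pass (adjusted p = 0.0588). It passed with no filter (0.0122), with the muscle arrays alone (0.0336), and without KI muscle replicate 94 (0.0341), KI cerebellum replicate 94 (0.0387) or KI cerebellum replicate 97 (0.0387). Among 16 amino acid response genes, the transporter Slc7a5 rose 2.11-fold (1.08 ± 0.15, adjusted p = 0.00801), and Vldlr (-0.72 ± 0.12, 0.0178) and the glutathione-degrading Chac1 (-0.91 ± 0.21, 0.0488) fell, with 1 higher and 3 lower adjusted over the list alone. Vldlr lost its call without any 1 muscle array (0.0663 to 0.0813), and Chac1 without KI muscle replicate 94 (0.203), WT muscle replicate 96 (0.158) or KI muscle replicate 97 (0.0654). Cth, of cysteine synthesis, was at -0.43 ± 0.10 (0.0536), and the list did not pass (adjusted p = 0.0689), except without KI muscle replicate 94 (0.0222) or WT muscle replicate 95 (0.0335).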
